A study of Oryza sativa with 3 samples.

How the data were processed

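Total RNA of rice was extracted with Trizol and made into paired-end libraries, 1 each from leaf blade, node (nodes I and II) and stem, per the labels. The plants grew at 29 °C in a greenhouse or growth chamber, in days of 12 h light at about 80000 lux and 12 h dark. Tissues were grouped by the labels alone. The stage and the hour of harvest were not given in the sources used here.

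The authors deposited, per library, an FPKM value per gene with a lower and an upper interval bound, a gene description and a locus, per the file headers. TopHat is named in the submitters' processing notes, with no version. The quantification program, the genome build and the annotation release were not given in the sources used here. FPKM divides fragments by transcript length and by the library's mapped fragments, so values depend on the length model used and on how the most abundant genes differ between libraries. Rows numbered 57615 in leaf blade, 57637 in node and 57562 in stem, with summed FPKM of 933658, 1008806 and 959926. The upper bound was read as FPKM + 2 × FPKM / √n, with n the number of fragments. Among rows under 200 fragments, n was whole within 0.02 for 49.2% in leaf blade, 49.2% in node and 49.7% in stem, against 4% by chance, so n is called an implied number and no count test was run. The summed n was 39880000 fragments in leaf blade, 39960000 in node and 43160000 in stem. The intervals were read as covering counting error only. A check chosen after the data were seen compared each 4-fold call with the shares of implied fragments, for genes above 0 in both tissues. These ran the other way for 10 of 2089 genes higher and 9 of 1242 lower in node versus leaf blade, 22 of 1119 and 14 of 1081 in stem versus leaf blade, and 13 of 1190 and 17 of 361 in node versus stem. Counting those, the shares fell short of 2-fold in the called direction for 45 and 44, 50 and 42, and 35 and 37 genes. The last was 10.3% of the genes lower in node versus stem. Whether length models or fragments shared among transcripts caused this was not analysed here.

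Genes are named by their locus identifiers as deposited. Symbols were attached by identifier, from lists written before the data were examined, and known roles are background. The gene table of another rice assembly matched 0 of 2000 identifiers tried and was not used further. Coordinates are those of the deposited loci. Their starts were taken to count from 0, because end minus start was a multiple of 3 for 42.2% of loci against 33.3% by chance, and 1 was added. This convention is inferred. Exons, introns and untranslated regions were not analysed here.

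Rows with no identifier numbered 3241, 3227 and 3016 in leaf blade, node and stem, and held 4.15%, 6.44% and 10.7% of summed FPKM. Rows of merged loci, with several identifiers, numbered 1220, 1231 and 1119, held 9.38%, 8.21% and 8.39%, and differed between libraries. Both kinds were left out. The 51597 genes with a single identifier, found once in each library, were kept, and the 20097 at 1 FPKM or more in at least 1 tissue were compared. Of these, 15.5% (3105) overlapped another row above 0 in some library. Strand was not given in the sources used here, so fragments of overlapping genes, and of near-identical copies, could be assigned to either. A value of 0 may be a failed estimate, so such genes are said to be listed at 0 and no fold is given against them.

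Differences are log2 ratios of (FPKM + 1). This pseudocount understates the differences of genes with low values. With 1 library per tissue no test between tissues was possible, and a gene counted as higher or lower at 4-fold or more. A gene predominated in a tissue where it was 4-fold or more above each of the others. The 3 comparisons were node versus leaf blade, stem versus leaf blade and node versus stem, and they share libraries, so they are not independent.

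Gene lists numbered 33, fixed before the data were examined: 20 by identifier and 13 by a pattern in the description. Of 199 members planned by identifier, 20 were absent or merged and 6 (BC10, GID2, YSL16, YSL15, D10 and AGPS2) were left out because the description contradicted the symbol, a judgement made with the values in view. Each list with 5 or more members compared was placed by its median among 10000 random lists of the same size, drawn with replacement and matched on mean expression in 20 bins. The 18 members compared of the list planned for lipid transfer and wax genes were described as 3-ketoacyl-CoA synthases, and the list is called by that name. A list stood apart under percentile 2.5 or over 97.5. Chance alone puts about 5% of lists of independently drawn genes beyond these bounds. Members of a list may vary together, which this does not cover, and percentiles describe these libraries only.

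Genes were named by a rule fixed beforehand. It took the 10 highest and 10 lowest log2 ratios per comparison among described genes at 10 FPKM or more in the higher tissue, and the 4 largest per list and comparison at 5 FPKM or more. It also took every mineral transporter and reference gene, the 10 most abundant genes per tissue, and 10 per tissue class. Descriptions naming transposable elements were excluded, a wording widened after 1 such gene ranked high. The rule gave 274 genes, of which a part is named. The values of 1 gene of the flowering list are not reported here.

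The calls were tested on simulated data, with Poisson counts at the implied depths. Of 100 genes changed 8-fold, 89 were recovered in node versus leaf blade, 86 in stem versus leaf blade and 87 in node versus stem, among 18031, 17035 and 17645 genes. Of 100 changed 16-fold, 100, 100 and 99 were recovered. Unchanged genes called numbered 5 of 17831, 4 of 16835 and 3 of 17445. Of 1000 random unchanged lists, 51, 42 and 42 fell beyond the bounds. The number of such lists was set to 1000 after a smaller run had been seen. The simulation holds no variation between plants.

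Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter at 5 FPKM, median ratio scaling on genes at 5 FPKM or more in all 3 tissues, scaling without the 50 most abundant genes of each tissue, and calls that also needed intervals that do not overlap. Including 542 merged loci common to all 3 libraries, and leaving out genes that overlap another row, were added after the data were examined. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.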

Results

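Gene expression was measured by sequencing total RNA from 3 tissues of rice (Oryza sativa), with 1 paired-end library each from the leaf blade, the node and the stem. Nodes are the joints of the grass stem where leaves attach and vascular bundles branch, and the node library came from nodes I and II. Each library gave an FPKM value (fragments scaled to the length of the transcript and the size of the library) with an interval for every gene. The implied number of fragments, to the nearest 10000, was 39880000 in leaf blade, 39960000 in node and 43160000 in stem. At this depth the interval of genes at 10 FPKM or more extended, at the median, 5.003% either side of the value in leaf blade, 5.05% in node and 4.79% in stem. These intervals were read as covering counting error only. There were no replicates, so no difference below has a replicate check and none has a p-value.

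Of 51597 genes present with a single identifier in all 3 libraries, 20097 reached 1 FPKM in at least 1 tissue and were compared, and 18736 were listed at 0 in all 3. The node expressed the most genes, with 18045 at 1 FPKM or more against 16584 in leaf blade and 16418 in stem. The most abundant gene with a specific description was, in leaf blade, the calvin cycle protein CP12 gene LOC_Os01g19740, at 10812 FPKM against 63.7 in node and 279 in stem. In node it was a metallothionein gene, LOC_Os01g74300, at 28298 FPKM against 338 in leaf blade and 4216 in stem. Metallothioneins are small cysteine-rich proteins that bind metals. In stem it was an RNA recognition motif gene, LOC_Os03g46770, at 10753 FPKM against 3857 in leaf blade and 13511 in node, though its implied fragments were the most numerous in leaf blade. The 10 most abundant of the genes with a single identifier held 12.4% of the FPKM summed over all rows in leaf blade, 13.6% in node and 6.81% in stem. Rows with no identifier are outside these shares, and the most abundant such row held 0.49% in leaf blade, 1.29% in node and 5.95% in stem.

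**Figure D1:**
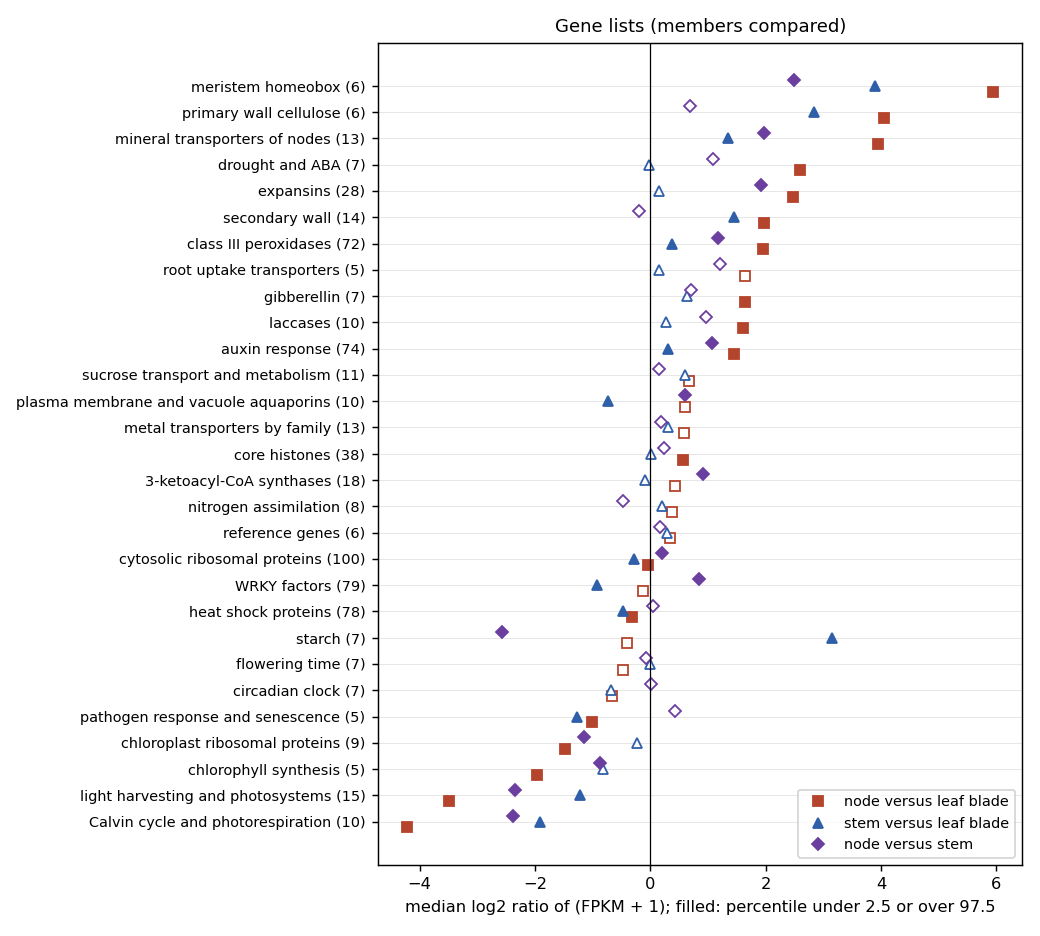
Median log2 ratio of (FPKM + 1) for the 29 gene lists with 5 or more members compared, with the number of members in brackets and a symbol for each of the 3 comparisons. Filled symbols mark medians in the lowest or highest 2.5% of 10000 random lists of matched expression; the meristem homeobox list lies farthest right at 5.94 and the Calvin cycle list farthest left at -4.21, both in node versus leaf blade.

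Lists of photosynthesis genes stood below random lists in node versus leaf blade. Mineral transporters already known from nodes, meristem regulators, cellulose synthases, drought genes and wall-loosening expansins stood above. All 15 light harvesting and photosystem genes compared were lower by 4-fold or more in node, and all 6 meristem homeobox genes were higher by 4-fold or more. Across the genes compared, 2472 were higher and 1466 lower in node by 4-fold or more, and 80.4% were within 4-fold. Of 29 gene lists with enough members for a percentile, 11 stood above and 7 below random lists of matched expression.

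Mineral transporters known from work on rice nodes had a median log2 difference of 3.95 in node versus leaf blade, above all 10000 random lists (percentile 100). Because the members were chosen for their known role in nodes, a high standing in node may follow from that choice. Metal transporters by family, chosen by description, were at percentile 87.23 in node versus leaf blade and 53.13 in node versus stem. Of 13 members compared, 8 were higher and 1 was lower by 4-fold or more. LSI2 (LOC_Os03g01700, chromosome 3, 430478 to 432878), a silicon efflux transporter, had 110.5 FPKM in node (interval 108 to 113) and 0.323 in leaf blade (0.212 to 0.434). Its relative LSI3 (LOC_Os10g39980, chromosome 10, 21417240 to 21419897) had 116 FPKM in node (113 to 119) and 0.146 in leaf blade (0.0681 to 0.224). The files describe both only as expressed proteins, so these symbols and roles rest on the identifiers alone. ZIP3 (LOC_Os04g52310, chromosome 4, 31078200 to 31080558), a zinc transporter, had 139 FPKM in node and 0.310 in leaf blade, a log2 difference of 6.74, and its locus overlapped another expressed row. HMA2, a zinc and cadmium pump (LOC_Os06g48720), had 23.5 FPKM in node against 0.0781, and the sodium transporter HKT1;5 (LOC_Os01g20160) had 30.1 against 0.653. The boron exporter BOR1 had 78.5 FPKM in node against 4.14 in leaf blade, and the phosphate exporter PHO1;2, whose locus also overlapped another row, had 38.4 against 0.462. HMA5, a copper pump, had 11.6 FPKM in node against 1.31. The silicon channel LSI6 was abundant in both tissues, at 626 FPKM in node and 241 in leaf blade, a log2 difference of 1.38 that was under 4-fold. SPDT, a phosphorus transporter, and the zinc transporter ZIP4 were also under 4-fold, with log2 differences of 1.87 and 1.98. The vacuolar transporter ABCC1 had a log2 difference of -0.90. LCT1, a cation transporter, went the other way, with 17.1 FPKM in leaf blade and 0.0498 in node.

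**Figure D2:**
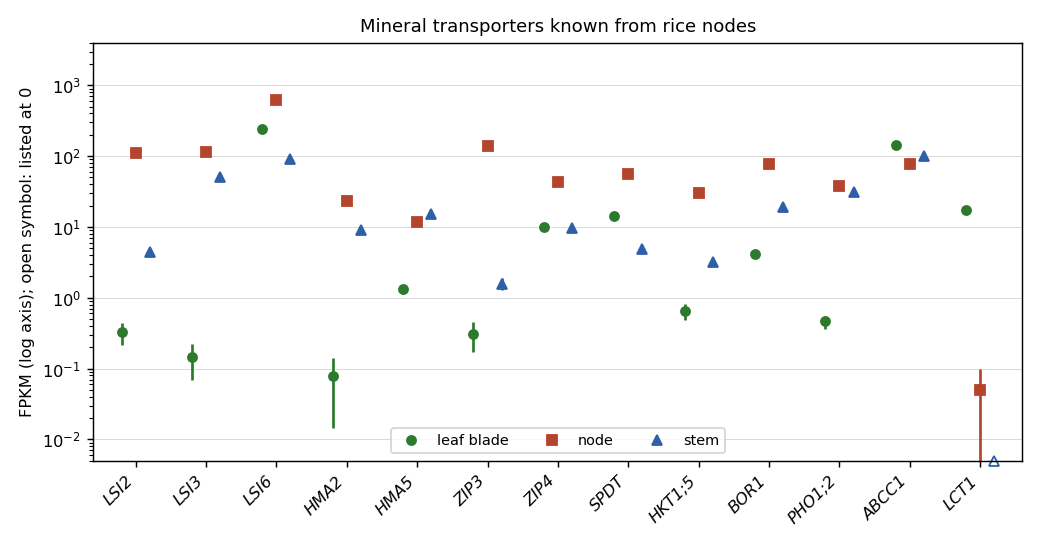
FPKM of the 13 mineral transporters compared, on a log axis, in 1 library each of leaf blade, node and stem, with vertical lines for the deposited intervals where they exceed the symbols. Node holds the highest of the 3 values for 10 of the 13 genes; LCT1 is listed at 0 in stem (open symbol) and the lower end of its node interval reaches 0, below the axis.

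Meristem homeobox and cell wall lists stood above random lists in node versus leaf blade. The 6 homeobox genes of the KNOTTED1-like and related classes, which act in meristems, had a median log2 difference of 5.94 (percentile 100). OSH1 (LOC_Os03g51690) had 131 FPKM in node against 0.192 in leaf blade, OSH15 (LOC_Os07g03770) had 145 against 0.284 and OSH71 (LOC_Os05g03884) had 110.1 against 0.103. All 6 cellulose synthases of the primary wall were higher in node by 4-fold or more (median 4.04, percentile 100), with CESA8 at 82.3 FPKM against 1.47. The secondary wall list had 7 of 14 members higher and none lower (median 1.97, percentile 100), among them CESA7 at 18.5 FPKM in node against 0.0411 and CESA4 at 21.1 against 0.205. Expansins, which loosen walls, had 16 of 28 members higher and 2 lower (median 2.47, percentile 100). Class III peroxidases had 34 of 72 higher and 9 lower (median 1.95, percentile 100). The peroxidase gene LOC_Os07g02440 had 92.7 FPKM in node against 0.212 in leaf blade, whereas LOC_Os02g14440 had 56.2 in leaf blade against 0.0197 in node. Laccases had 3 of 10 higher (median 1.60, percentile 99.49). That list's percentile was 97.40 with a pseudocount of 0.1 and 87.42 with a filter at 5 FPKM.

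Hormone and drought lists also stood above random lists in node. Auxin response genes had 31 of 74 members higher and 3 lower (median 1.46, percentile 100). The SAUR gene LOC_Os09g37500 had 66.2 FPKM in node against 0.0391 in leaf blade, and its neighbour LOC_Os09g37480 had 63.2 in node and was listed at 0 in leaf blade. Gibberellin genes had 2 of 7 higher and none lower (median 1.64, percentile 99.78), namely GA2OX3, which inactivates gibberellin, at 201 FPKM against 7.10, and GA20OX1, which acts in its synthesis, at 65.9 against 7.22. Genes of drought and abscisic acid had 5 of 7 higher (median 2.60, percentile 100), with the dehydrin gene DIP1 at 998 FPKM in node against 55.0 in leaf blade. Core histones had 11 of 38 higher and 1 lower (median 0.57, percentile 99.06), and the percentile was 93.58 with no filter on low values.

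Photosynthesis lists stood below random lists in node. Light harvesting and photosystem genes had a median log2 difference of -3.49 (percentile 0.00), with CAB1R, an antenna protein gene, at 163 FPKM in node against 4277 in leaf blade. Calvin cycle and photorespiration genes had 9 of 10 members lower (median -4.21, percentile 0.00), with the chloroplast fructose-bisphosphatase cpFBPase1 at 1.81 FPKM in node against 170.3 and the photorespiratory oxidase GLO1 at 9.48 against 423. Chlorophyll synthesis had 2 of 5 lower (median -1.96, percentile 0.23). Chloroplast ribosomal proteins had 2 of 9 lower (median -1.48, percentile 0.04). Heat shock proteins, 47 of them described as DnaJ proteins, had 15 of 78 lower and 4 higher (median -0.32, percentile 0.04), and pathogen response and senescence genes had 1 lower and 1 higher of 5 (median -1.01, percentile 2.22). Cytosolic ribosomal proteins had no member beyond 4-fold (median -0.04, percentile 0.88), and the percentile was 2.78 with no filter on low values. Among single genes, the osmotin gene LOC_Os12g38170 had 694 FPKM in leaf blade and 0.773 in node. The aquaporin PIP2;7 (LOC_Os09g36930) had 1579 FPKM in leaf blade and 3.09 in node. At the other end, the highest log2 difference by the naming rule was 9.42, for LOC_Os08g39330, described as a skin secretory protein xP2 precursor, with 1279 FPKM in node and 0.874 in leaf blade.

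Other lists held genes with large differences between node and leaf blade, but their medians did not stand apart. The sucrose synthase SUS1 (LOC_Os03g28330) had 499 FPKM in node and 2.63 in leaf blade, and the sugar exporter SWEET11 had 17.04 against 0.0148, within a sucrose list of 11 with a median of 0.67 (percentile 91.53). Nitrogen assimilation had 3 of 8 higher and 2 lower (median 0.38, percentile 80.04), with the chloroplast glutamine synthetase GS2 at 3.69 FPKM in node against 168 in leaf blade and the asparagine synthetase ASN1 at 51.8 against 1.23; the ASN1 locus overlapped another row. Flowering genes had 2 of 7 higher and 1 lower (median -0.47, percentile 8.46). The floral transition gene MADS15 (LOC_Os07g01820) had 0.542 FPKM in leaf blade and 121 in node. WRKY factors had 10 of 79 higher and 15 lower (median -0.13, percentile 2.81); the percentile was under 2.5 under 5 other settings, at 0.42 to 2.49. Starch (median -0.41, percentile 9.66), circadian clock genes (-0.67, 3.38), the 10 listed aquaporins (0.61, 90.20), metal transporters by family (0.59, 87.23), and 3-ketoacyl-CoA synthases (0.43, 72.05) also lay within the bounds.

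A gene counted as higher or lower at a log2 difference of 2 or more on the log2(FPKM + 1) scale, which understates differences of genes with low values. Of the 2472 genes higher in node, 383 were listed at 0 in leaf blade, and the median over the genes compared was 0.13, or 0.03 when the libraries were rescaled without their 50 most abundant genes.

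The stem resembled the leaf blade more in photosynthesis than the node did, and it differed from the leaf blade in starch genes, of synthesis and of breakdown. Starch genes had 5 of 7 members higher and 2 lower in stem than in leaf blade by 4-fold or more. The branching enzyme gene BEIIA is counted among the 2 lower, but its implied fragments ran the other way, so its direction is uncertain. The lists of meristem homeobox, cellulose and secondary wall genes stood above random lists, and those of WRKY factors and heat shock proteins below. The counts were nearly even, with 1292 genes higher and 1310 lower in stem, and 87.1% within 4-fold. Of the 29 lists, 7 stood above and 7 below random lists.

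The starch list had a median log2 difference of 3.16 in stem versus leaf blade (percentile 100). AGPL1 (LOC_Os05g50380, chromosome 5, 28871794 to 28877277), a large subunit of ADP-glucose pyrophosphorylase, the enzyme that makes the glucose donor of starch, had 1502 FPKM in stem (interval 1492 to 1512) and 10.7 in leaf blade (9.85 to 11.5). GBSSII (LOC_Os07g22930), a granule-bound starch synthase, had 560 FPKM in stem against 61.9, and the starch synthase SSI had 64.8 against 13.7. The beta-amylase BMY and the alpha-amylase AMY2A, which break starch down, had 31.9 and 22.3 FPKM in stem against 1.66 and 1.24. The branching enzyme BEIIA (LOC_Os04g33460) and another large subunit, AGPL3 (LOC_Os03g52460), were lower in stem, at 26.3 FPKM against 291 and 4.30 against 66.9. For BEIIA the implied fragments ran the other way, with 1436 in stem and 87.1 in leaf blade, so its direction is uncertain.

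**Figure D3:**
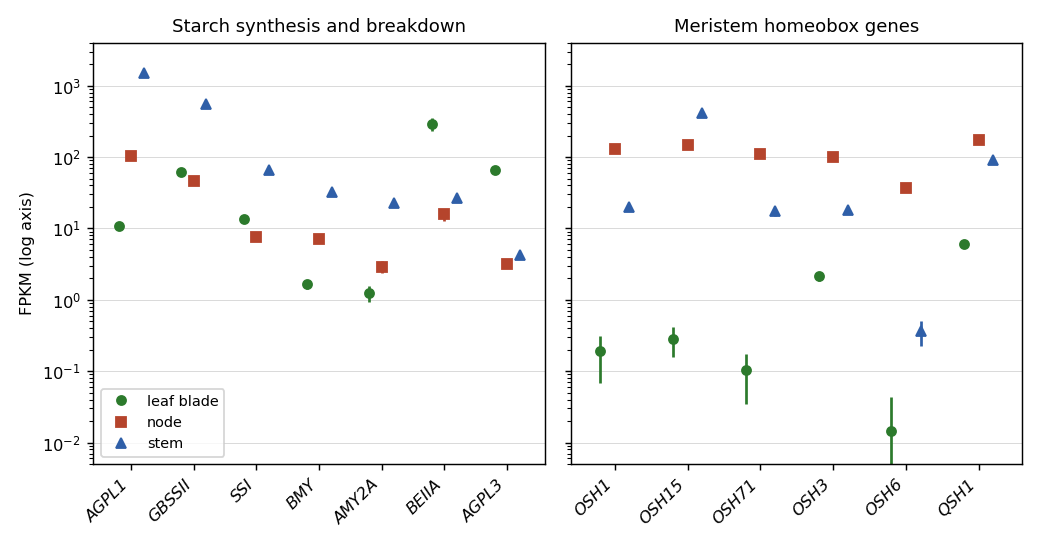
FPKM of the 7 starch genes (left) and the 6 meristem homeobox genes (right), on a log axis, in 1 library each of leaf blade, node and stem, with vertical lines for the deposited intervals where they exceed the symbols. AGPL1 reaches 1502 FPKM in stem against 104 in node and 10.7 in leaf blade; OSH15 is highest in stem and the other 5 homeobox genes in node, and the lower end of the leaf blade interval of OSH6 reaches 0, below the axis.

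Homeobox, primary and secondary wall, mineral transporter, peroxidase and auxin response lists stood above random lists in stem versus leaf blade. Of 6 meristem homeobox genes, 5 were higher (median 3.89, percentile 100), with OSH15 at 411 FPKM against 0.284 and OSH1 at 19.6 against 0.192. The other gene, OSH6, had 0.365 FPKM in stem and 0.0143 in leaf blade, which was under 4-fold on this scale. Primary wall cellulose synthases had 3 of 6 higher and none lower (median 2.83, percentile 99.99), with CESA1 at 65.4 FPKM against 4.17 and CESA3 at 110.8 against 6.16. The secondary wall list had 5 of 14 higher and none lower (median 1.45, percentile 99.98). CESA9 (LOC_Os09g25490) had 34.3 FPKM in stem against 0.0566 in leaf blade, and the lignin enzyme CAD2 had 130.5 against 27.5. Mineral transporters had 5 of 13 higher and 1 lower (median 1.35, percentile 99.97), with LSI3 at 51.0 FPKM in stem, PHO1;2 at 30.9 and HMA2 at 8.99. Class III peroxidases had 18 of 72 higher and 10 lower (median 0.37, percentile 99.99); with no filter on low values the median was 0.00 and the percentile 52.71. Auxin response genes had 8 of 74 higher and 5 lower (median 0.30, percentile 99.74), with the auxin efflux carrier LOC_Os09g31478 at 228 FPKM in stem against 21.8.

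Photosynthesis differed by less in stem versus leaf blade than in node versus leaf blade. Light harvesting and photosystem genes had 4 of 15 members lower (median -1.23, percentile 0.00). CAB1R had 668 FPKM in stem against 4277 in leaf blade, while CAB2R had 2741 against 1999. Calvin cycle and photorespiration genes had 5 of 10 lower (median -1.91, percentile 0.00), and the chloroplast aldolase FBAcp was at 961 FPKM in stem against 406. The Rubisco small subunit gene RBCS4 was listed at 0 in stem and at 149.7 FPKM in leaf blade; it has near-identical copies that could share its fragments. WRKY factors had 17 of 79 lower and 5 higher (median -0.93, percentile 0.00), with WRKY76 at 0.223 FPKM in stem against 178. Heat shock proteins had 16 of 78 lower and 3 higher (median -0.48, percentile 0.01). Pathogen response and senescence genes had 2 of 5 lower and 1 higher (median -1.26, percentile 0.84). The listed aquaporins had 1 of 10 lower and 2 higher (median -0.74, percentile 0.49), and PIP2;7 was at 0.122 FPKM in stem against 1579; the percentile of this list was 3.60 with a pseudocount of 5 and 4.89 with a filter at 5 FPKM. Cytosolic ribosomal proteins had 2 of 100 higher and none lower (median -0.29, percentile 0.00).

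The other lists did not stand apart in stem versus leaf blade. In the sucrose list, SUS1 had 109.6 FPKM in stem against 2.63 and SWEET14 had 27.5 against 2.715 (median 0.61, percentile 94.12). Nitrogen assimilation (median 0.21, percentile 72.34) held NADHGOGAT1, a glutamate synthase, at 222 FPKM in stem against 15.3, and FDGOGAT, its ferredoxin-dependent counterpart, at 35.1 against 323. The implied fragments of both ran the other way, at 3062 in stem against 5358 for NADHGOGAT1 and 10660 against 9149 for FDGOGAT, so these directions are uncertain. Flowering genes (median -0.01, percentile 46.93) held MADS15 at 127 FPKM in stem against 0.542. Gibberellin genes (0.64, 95.88), chlorophyll synthesis (-0.81, 5.04), chloroplast ribosomal proteins (-0.23, 23.45), expansins (0.14, 88.05), laccases (0.27, 90.06), core histones (0.02, 54.82), drought and abscisic acid genes (-0.03, 44.14), circadian clock genes (-0.67, 3.52), metal transporters by family (0.31, 91.43), and 3-ketoacyl-CoA synthases (-0.08, 41.18) had the medians and percentiles given. The core histone median was -0.01 and the flowering median 0.03 under a rescaling each. Outside the lists, the cytochrome P450 gene LOC_Os03g45619 had 224 FPKM in stem and 0.134 in leaf blade, and the chalcone synthase gene LOC_Os11g32650 had 176 and 0.440.

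By the same 4-fold rule the counts higher and lower were 2417 and 2285 with a pseudocount of 0.1, and 582 and 542 with 5, and genes higher were also the more numerous with median ratio scaling, a filter at 5 FPKM or overlapping genes left out, so which was larger depended on the setting. Of the 1310 genes lower in stem, 229 were listed at 0 in stem, and of the 1292 higher, 173 were listed at 0 in leaf blade.

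Node and stem were the most similar pair, with 90.9% of genes within 4-fold, and most of the larger differences were toward the node. There 1370 genes were higher and 463 lower in node. The lists of mineral transporters, meristem homeobox genes, expansins, auxin response genes and peroxidases stood above random lists, as did WRKY factors except with no filter on low values, while starch and photosynthesis lists stood below. Of the 29 lists, 9 stood above and 5 below random lists.

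Mineral transporters had 6 of 13 members higher and none lower in node than in stem (median 1.97, percentile 100). ZIP3 had 139 FPKM in node (interval 136 to 143) against 1.57 in stem (1.27 to 1.87), and LSI2 had 110.5 against 4.40. SPDT (LOC_Os06g05160) had 55.3 against 4.89, HKT1;5 had 30.1 against 3.23, LSI6 (LOC_Os06g12310) had 626 against 92.2 and ZIP4 had 42.5 against 9.72. The call for ZIP4 ended under both rescalings, at 1.96 and 1.98. BOR1, HMA2, LSI3 and PHO1;2 were also higher in node but by less than 4-fold, with log2 differences of 1.97, 1.29, 1.17 and 0.31, and for HMA2 and LSI3 the implied fragments were slightly more numerous in stem. HMA5 and ABCC1 had log2 differences of -0.37 and -0.38.

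Meristem homeobox, expansin, auxin response and peroxidase lists stood above random lists in node versus stem. Meristem homeobox genes had 4 of 6 higher in node and none lower by 4-fold (median 2.496, percentile 100). OSH6 had 37.1 FPKM in node against 0.365 in stem, and OSH1 had 131 against 19.6, whereas OSH15 had 145 against 411. Expansins had 14 of 28 higher and none lower (median 1.92, percentile 100). The expansin gene LOC_Os05g39990 had 166 FPKM in node against 0.580, and LOC_Os01g60770 had 105.6 against 0.319. Auxin response genes had 20 of 74 higher and 4 lower (median 1.07, percentile 100); the efflux carrier LOC_Os08g41720 had 247 FPKM in node against 5.81, while the carrier LOC_Os09g31478 had 42.3 against 228. Class III peroxidases had 23 of 72 higher and 3 lower (median 1.17, percentile 100), with LOC_Os03g32050 at 43.8 FPKM in node against 0.109. The family 16 glycosyl hydrolase genes LOC_Os11g33270 and LOC_Os07g29750 had 276 and 134 FPKM in node against 0.240 and 0.679 in stem. The bHLH gene LOC_Os03g07540 had 195 FPKM in node against 0.454. The aspartic proteinase gene LOC_Os09g30414 had 269 FPKM in node and was listed at 0 in the other tissues, where a merged row spanned its locus.

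WRKY factors had 13 of 79 higher and none lower in node than in stem (median 0.85, percentile 100), with WRKY2 (LOC_Os10g42850) at 63.8 FPKM against 2.60; with no filter on low values the percentile was 95.97. Cytosolic ribosomal proteins had none of 100 higher and 1 lower (median 0.20, percentile 99.19). The listed aquaporins had 1 of 10 higher (median 0.60, percentile 98.79), with PIP1;3 at 187 FPKM in node against 18.0, and the percentile was 96.39 with a filter at 5 FPKM. The 3-ketoacyl-CoA synthases, which make precursors of waxes, had 4 of 18 higher (median 0.92, percentile 98.66), with percentiles of 96.00 to 97.33 under 3 other settings.

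Starch and photosynthesis lists stood below random lists in node versus stem. Starch genes had 5 of 7 lower and none higher (median -2.57, percentile 0.00), with AGPL1 at 104 FPKM in node against 1502 and GBSSII at 46.5 against 560. Light harvesting and photosystem genes had 9 of 15 lower (median -2.34, percentile 0.00), with LHCB3 at 73.4 FPKM in node against 675.5. Calvin cycle and photorespiration genes had 6 of 10 lower and 1 higher (median -2.38, percentile 0.00), the higher gene being RBCS4, at 7.26 FPKM in node and listed at 0 in stem. Chlorophyll synthesis (median -0.87, percentile 1.01) had no member beyond 4-fold and chloroplast ribosomal proteins (median -1.15, percentile 0.03) had 1 of 9 lower. The plastocyanin-like gene LOC_Os11g24140 had 319 FPKM in stem and 8.40 in node.

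The remaining lists did not stand apart in node versus stem. Secondary wall genes had 1 of 14 higher and 1 lower (median -0.20, percentile 5.82), with CESA4 at 21.1 FPKM in node and 18.0 in stem. The higher gene, BC12, had a log2 difference of 2.03 but 1260 implied fragments in node and 1430 in stem. CESA9 had a log2 difference of -1.20 but 2447 implied fragments in node and 1171 in stem. The directions of BC12 and CESA9 are uncertain. Primary wall cellulose (0.69, 94.06), laccases (0.96, 92.23), gibberellin (0.70, 94.06), drought and abscisic acid (1.09, 96.28), nitrogen assimilation (-0.47, 4.11), sucrose (0.15, 60.27), flowering (-0.07, 22.89), pathogen response and senescence (0.43, 89.73), core histones (0.24, 87.61), heat shock proteins (0.04, 12.96) and metal transporters by family (0.19, 53.13) had the medians and percentiles given. The 1 nitrogen gene lower by 4-fold, NADHGOGAT1, had a log2 difference of -3.28 but 7464 implied fragments in node and 3062 in stem. Its direction is uncertain. For circadian clock genes the median was 0.01 (percentile 44.38), and that median was below 0 under both rescalings. Within these lists, SWEET11 had 17.04 FPKM in node against 0.182 in stem, the gibberellin synthesis gene SD1, whose locus overlapped another row, had 66.8 against 3.19, and the florigen gene HD3A had 21.2 against 1.17. The genes higher by 4-fold included 180 listed at 0 in stem, and those lower included 102 listed at 0 in node.

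By the same 4-fold rule against each other tissue, 1058 genes predominated in node, 916 in leaf blade and 185 in stem. With a pseudocount of 5 the counts were 391, 394 and 74, so the order of node and leaf blade depended on it. Node genes included the expansins, family 16 hydrolases and bHLH gene above, the glycine-rich wall protein gene LOC_Os02g37480, at 158 FPKM in node against 0.0826 in leaf blade and 0.199 in stem, and the gibberellin-regulated gene LOC_Os03g55290, at 382 against 1.79 and 2.57. Leaf blade genes included osmotin, the tyrosine aminotransferase gene LOC_Os02g20360, at 149.7 FPKM against 0.407 in node and 0.211 in stem, and the terpene synthase gene LOC_Os04g27790, at 138 against 0.171 and 0.607. Stem genes included the cytochrome P450 gene LOC_Os03g45619 and the O-methyltransferase gene LOC_Os05g43930, at 118.5 FPKM against 0.271 in leaf blade and 4.69 in node.

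Reference genes commonly used in rice had no member beyond 4-fold in any comparison, with list medians of 0.34 in node versus leaf blade (percentile 66.22), 0.30 in stem versus leaf blade (65.64) and 0.16 in node versus stem (70.34). ACT1 differed most among them, with 65.4 FPKM in leaf blade, 168 in node and 129 in stem, while TIP41 had 19.6, 18.0 and 20.3. Markers of other organs were also read. Root uptake transporters had a median of 1.65 in node versus leaf blade (percentile 93.60), 0.15 in stem versus leaf blade (68.08) and 1.21 in node versus stem (93.51). LSI1, a silicon channel of roots, had 38.5 FPKM in node, 11.6 in leaf blade and 8.055 in stem. Of 9 floral organ identity genes, 2 were compared: MADS16 had 91.3 FPKM in node, 38.0 in stem and 8.93 in leaf blade, and MADS1 had 0.391, 0.457 and 11.7. Of 4 genes of the mitotic list, the cyclin-dependent kinase B2-1 gene LOC_Os08g40170 differed most, with 15.2 FPKM in node, 3.16 in stem and 0.692 in leaf blade, and the list medians were 0.45, 0.21 and 0.49 in the order of comparisons above. The pattern for this list took in only genes described as B-type cyclin-dependent kinases or cyclin-A1. Genes described only as cyclins or kinesin motor proteins fell outside it, so its medians do not cover mitotic genes at large. The strigolactone list of 4 genes had medians of 1.59, 1.25 and 0.32, and the 2 genes of the wall NAC and MYB list had medians of 2.30, 0.31 and 1.99.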

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

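All tests of the homeobox genes and of the rows with no identifier were chosen after those results were seen; the test of genes listed at 0 was set before, except that its interval was added to the decision after the share of 36% was known.

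Rows with no gene identifier lay outside the comparisons, and their share of summed FPKM was 4.15% in leaf blade, 6.44% in node and 10.7% in stem. These rows held 1.67% of implied fragments in stem, and loci shorter than 200 bases held 72.8% of their FPKM there, so the larger share in FPKM may come from short loci with few fragments. A locus on chromosome 10, from 2755965 to 2756070, was at 57111 FPKM in stem (interval 30189 to 84034) from 18 implied fragments, or 5.95% of the library's FPKM. Without the most abundant such row of each library the share was 5.04% in stem and 5.21% in node, so the stem share stood above the node share only with that locus included. No biological explanation was tested.

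The meristem homeobox list was higher in node than in stem, with a median log2 ratio of 2.496 over 6 genes, of which 4 were higher by 4-fold or more and OSH15 had a log2 ratio of -1.49. With median ratio scaling the log2 ratio of the node and stem scaling factors was only -0.066, which left the list median at 2.43. A factor of that size argues against overall scaling of the libraries as the source of the difference. A candidate explanation is dividing tissue in the node sample. The 127 genes chosen by wording for DNA replication and division had a median of 0.73 in node versus stem (percentile 100, random lists 0.22). Of these, 103 lay above 0 and 8 were higher by 4-fold or more, against 1370 of all 20097 genes compared. Their median was 0.11 in stem versus leaf blade (percentile 97.21). The wording also took in cyclin-dependent kinases of every kind, their inhibitors and any kinesin motor gene. So the set is broader than division. The pseudocount also understates differences of its low members. Every minichromosome maintenance (MCM) gene in the set was higher in node than in stem. MCM5 had 2.36 FPKM in node against 0.152 in stem, and MCM2 had 3.59 against 2.29. These low values were read afterwards and come from 1 library per tissue. The set therefore cannot decide whether the node sample held dividing tissue. The core histone list fixed beforehand did not stand apart in node versus stem (median 0.24 over 38 genes, percentile 87.61). A part of that list, the 21 genes described by the core histone domain, did (median 0.55, percentile 99.43). This part was read afterwards, so it is not separate support. With 1 library per tissue, a difference between these libraries other than tissue cannot be told apart from tissue, and the anatomy of the samples stays untested.

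Between libraries, 25 genes were listed at 0 in 1 tissue and at 20 FPKM or more in the others, 18 of them at 0 in leaf blade, 3 in node and 4 in stem. Fragments assigned to another row over the same place are a possible explanation: 9 of the 25, or 36% (exact 95% interval 18.0 to 57.5), overlapped another row above 0 in that library, against 6.10% of gene and library pairs at 20 FPKM or more in every tissue. This explanation cannot be told apart from others for the set, because the interval spans 50%, the bound set for arguing against it, and 16 genes had no such overlap. Those 16 include the histone gene LOC_Os03g17084, at 0 in leaf blade and at 104 FPKM in node and 112 in stem, and the Bowman-Birk inhibitor gene LOC_Os01g03390, at 66.7 and 582. Expression confined to some tissues stays open and was not tested.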

How the results depend on the processing

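Including merged loci and leaving out genes that overlap another row were settings chosen after the data were seen. No list that stood apart in the main setting changed direction, although the peroxidase median was 0.00 in 1 case below. Some list medians within the bounds changed sign. No named gene past the 4-fold rule changed direction, but these settings could hardly reverse one. Another pseudocount keeps the sign of a difference, and the log2 ratio of scaling factors largest in size was -0.13. Shares of implied fragments ran the other way for some named calls, such as BEIIA and NADHGOGAT1 in stem versus leaf blade. Counts of genes stayed within 1.5 times their main value in 60 cases and moved further in 18, all with another pseudocount, which by construction widens or narrows differences of low genes. With a pseudocount of 0.1 the counts higher and lower were 3976 and 2273 in node versus leaf blade, 2417 and 2285 in stem versus leaf blade, and 2672 and 882 in node versus stem, and 1534, 1932 and 337 genes predominated in leaf blade, node and stem. With a pseudocount of 5 they were 1080 and 672, 582 and 542, and 483 and 183, and 394, 391 and 74. List medians kept their side of the bounds in 645 cases, moved beyond them in 27 and within them in 12. Named genes kept their side of the 4-fold rule in 3827 cases, passed it in 61 and lost it in 105. Counting error limits low genes most, and the lack of replicates limits all genes.

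For the lists that changed, the cause was not tested, and the medians under the alternatives follow. In node versus leaf blade the lists that moved within the bounds were cytosolic ribosomal proteins (-0.013) and core histones (0.13) with no filter, and laccases with a pseudocount of 0.1 (3.58) and a filter at 5 FPKM (2.22). Those that moved beyond them were root uptake transporters with a pseudocount of 5 (1.04), metal transporters by family with a filter at 5 FPKM (1.09), and WRKY factors with a pseudocount of 5 (-0.082), no filter (-0.026), median ratio scaling (-0.20), scaling without the 50 most abundant genes (-0.25) and overlapping genes left out (-0.26).

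In stem versus leaf blade, peroxidases with no filter (0.00) and aquaporins with a pseudocount of 5 (-0.38) or a filter at 5 FPKM (-0.48) moved within the bounds. Beyond them moved, with a pseudocount of 0.1, sucrose (1.20), gibberellin (1.52), expansins (0.78) and laccases (1.47); with a filter at 5 FPKM, laccases (2.09), metal transporters by family (1.34) and 3-ketoacyl-CoA synthases (-1.27); gibberellin without the 50 most abundant genes (0.75); and metal transporters by family without overlapping genes (0.78).

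In node versus stem, aquaporins with a filter at 5 FPKM (0.50), WRKY factors with no filter (0.19), and 3-ketoacyl-CoA synthases with a pseudocount of 5 (0.34), a filter at 5 FPKM (0.81) or overlapping genes left out (0.84) moved within the bounds. Beyond them moved secondary wall (-0.44) and nitrogen assimilation (-0.63) without overlapping genes, and root uptake transporters (0.84) and drought and abscisic acid (0.79) with a pseudocount of 5. Gibberellin did so with a pseudocount of 0.1 (1.43), a filter at 5 FPKM (1.48) and without the 50 most abundant genes (0.83). So did drought and abscisic acid with no filter (1.09) and without the 50 most abundant genes (1.51), laccases with no filter (0.070), and metal transporters by family with no filter, below the lower bound (-0.17, against 0.19 in the main setting).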

Other observations

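The scan of families and its order were chosen after the data were seen. Gene families named by the shared wording of their descriptions, each with 10 or more genes compared, numbered 269. In node versus leaf blade 63 stood above and 23 below random lists, in stem versus leaf blade 37 and 23, and in node versus stem 53 and 24. Genes drawn independently would give about 13.5 in all per comparison. Genes of a family may vary together, which that number does not cover. RALF peptides, small secreted signals that raise the pH outside cells, had 16 of 22 genes higher in node than in leaf blade and 3 lower (median 3.76, percentile 100). Fasciclin domain proteins, found at cell walls and membranes, had 9 of 11 higher (median 3.27, percentile 100), and dirigent proteins, which steer the coupling of lignin and lignan precursors, had 13 of 20 higher and none lower (median 2.13, percentile 100). Tubulins were higher in stem than in leaf blade (9 of 15, median 2.86, percentile 100). The same held in node versus leaf blade (8 of 15, median 2.06, percentile 100). RALF, fasciclin and dirigent genes also stood above random lists in stem versus leaf blade (medians 1.455, 2.39 and 0.84). The LTP and protease inhibitor family had 29 of 64 genes higher in node than in stem and 1 lower (median 1.76, percentile 100). Aquaporins taken by description had 7 of 23 genes higher and 2 lower in node versus leaf blade (median 1.31, percentile 100), where the 10 listed by identifier had a median of 0.61. In stem versus leaf blade, heat shock DnaJ proteins had 10 of 47 lower and 1 higher (median -0.45, percentile 0.39), while the 12 small heat shock proteins of the hsp20 family had 2 higher and 2 lower (median 0.41, percentile 91.35).

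Lower families were fewer. OsWAK receptor-like kinases, which bind the cell wall, had 5 of 22 genes lower and none higher in node versus leaf blade (median -1.29, percentile 0.00) and in stem versus leaf blade (median -1.59, percentile 0.00). CCT/B-box zinc finger proteins had 6 of 17 lower and 1 higher in both (medians -1.18 and -1.39). Pentatricopeptide proteins, which process organelle RNA, had a median of -0.34 over 110 genes in node versus leaf blade, with 3 lower and 2 higher by 4-fold.

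The clock genes LHY and LUX were at 15.4 and 11.3 FPKM in leaf blade, 134 and 1.46 in node, and 47.2 and 1.91 in stem. In node versus leaf blade these were log2 differences of 3.04 and -2.32, opposite movements that the list median does not show. Levels of clock genes depend on the hour of harvest, which was not given. An effect of the hour cannot be told apart from tissue here. MADS14, whose locus overlapped another row, was at 89.8 FPKM in leaf blade, 713 in node and 743 in stem.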
